A study of Mus musculus with 6 samples.

How the data were processed

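Scar tissue of the left ventricle was collected 6 weeks after infarction from mice with floxed Sox9 alleles, without (control) or with (Sox9 deletion) a Cre labelled Per-Cre, and RNA was sequenced from 3 libraries of each group. Per the labels' protocols, RNA was purified with RNeasy columns and libraries were made from 100 ng of total RNA with the ScriptSeq v2 kit. The series text speaks of polyadenylated RNA while the molecule given in the labels is total RNA, and the sources used here do not settle which applies. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

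The deposited table holds raw read counts per gene, per the file headers. Trim Galore, STAR and deepTools and the mouse build mm10 are named per the submitters' processing notes, without their role, order or version. The counting tool and its use of strand are not given in the sources used here. The table also holds the authors' deposited signal values, called TMM per the file headers, with their means per group, a deposited log2 fold change equal to the log2 ratio of these means, and the authors' NOISeqBIO probability, a score from 0 to 1. It lists 14798 genes, and the lowest mean count of a listed gene is 7, so genes of low expression appear to have been left out before deposition. Mitochondrially encoded genes are absent. Genes carry 1 RefSeq transcript each and coordinates in mm10.

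Counts were analysed in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 (TMM factors, filterByExpr by group, robust fit, prior count of 2 for log2 values), with genotype as the only term and a Benjamini-Hochberg adjusted p below 0.05 as the threshold. The fit left 4 residual degrees of freedom, and 14771 genes were tested. CPM values are TMM-scaled, ± gives the SD of 3 libraries for CPM and the standard error for log2 fold changes, and log2 fold changes are deletion minus control. With 3 libraries against 3, an exact permutation test of a single value cannot give a p below 0.1, so none was used for single genes. Total counts ran from 18538171 to 55523974 per library as deposited, where those of replicates 2 and 3 may be doubled, and the standard errors printed beside the log2 fold changes give the precision reached.

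The tests, thresholds, lists and naming rule below were fixed before the data were examined. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it, and adjusted over the lists. The 38 lists covered non-cartilage collagens, collagen processing, cartilage matrix and SOX9 targets, matricellular proteins, proteoglycans, matrix proteases, fibroblast markers, myofibroblast and smooth muscle genes, TGF-beta signalling, Wnt signalling and the SOX family. They also covered cytokines, macrophages, monocytes and neutrophils, T and natural killer cells, B and plasma cells, mast cells, antigen presentation, complement and interferon-stimulated genes. The others were cardiomyocyte genes, cardiac stress genes, fatty acid oxidation, oxidative phosphorylation, mitochondrially encoded genes, endothelium, lymphatic endothelium, pericytes, epicardium, adipocytes, Schwann cells, erythrocytes, skeletal muscle, bone and calcification, epithelium, proliferation, immediate early genes and ribosomal proteins. Of these, 37 had measured members, 19 passed at the preset correlation (4 up and 15 down), and 0 passed with the estimated correlation or with fry. A list's score per library is the mean log2 CPM of its members minus the mean over the 6 libraries. Single members were adjusted over all genes tested and, separately, over the list alone.

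Genes named in the text follow a rule with a fallback that applied because no gene passed. It named Sox9 and Postn, the 5 genes with the largest rise and the 5 with the largest fall in log2 fold change among the 100 smallest p-values, predicted gene models left out, and the 2 members with the highest mean expression of each list. Of these, 2 genes are not reported here; they stay in the tests of their lists. Outside the rule, Rn45s, Xist, Ddx3y, Myot, Col2a1, Acan, Col9a2, Eln, Ppara, Ppargc1a and S100b were named after their values were seen. Of the 85 genes checked for overlaps against GENCODE vM21, 83 were matched, and 24 share exonic bases with another annotated gene, 10 with a gene on the same strand and 18 with a gene on the opposite strand. These include Timp3 with Syn3, Myh7 with Mhrt, Muc4 with Muc20 and Xist with Tsix. Values of overlapping genes and of near-identical copies (Hba-a1, Hba-a2, Ccl21a) are uncertain, since reads could be split between them.

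Replicates 2 and 3 of both groups hold only even counts and replicate 1 of both groups does not; this split is called the batch here, although the labels name none and the even counts may come from the way mates were counted. Alternatives added after this was seen were a batch term, replicates 2 and 3 alone, halved counts, DESeq2 and limma with a batch term, limma on the authors' values (log2 with a pseudocount of 1), on log2 CPM and on log2 CPM after subtraction of the batch, an adjusted p below 0.10 with the batch term, and the cardiomyocyte score as a covariate. Alternatives fixed beforehand were DESeq2 1.42.0, its size factors in edgeR, no filter, the replicate number as a block, each library left out in turn, thresholds of 0.01 and 0.10, a minimum absolute log2 fold change of 1, coding transcripts only, a median log2 fold change of 0, and restricted list members. All 6 libraries were kept in the fits unless stated.

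The analysis was tested on simulated data with 200 changed genes, all drawn from genes at or above the median mean count. Recovery of changed genes below that median was not tested. With genotype alone, 24 of 100 genes simulated at a 2-fold difference and 90 of 100 at 4-fold were recovered, and 7 of 14541 unchanged genes were called. With the batch term these were 86 and 98 of 100, and 17 of 14542. The data simulated for genotype alone held no shift of replicate 1 against replicates 2 and 3. The batch entered them only as added spread between libraries, so recovery in the real data may differ. A list shifted by -1 on the log2 scale was recovered, and 0 of 36 others were called with camera at the preset correlation. Genes were simulated independently of each other, whereas the median estimated correlation within lists was 0.427 in the data. The simulation therefore cannot show how often camera at the preset correlation calls unchanged lists here. In the data, other splits of the 6 libraries into 3 and 3 gave 14 to 25 list calls, against 19 for the real split. A call at the preset correlation therefore does not by itself set the genotypes apart. Intervals of medians over genes are 95% bootstrap intervals from 10000 draws; they treat genes as independent and do not include the spread between libraries.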

Results

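RNA was sequenced from the infarct scar of the mouse left ventricle, taken 6 weeks after ligation of the left anterior descending coronary artery at 10 weeks of age. The labels give the tissue donors as 14 to 16 weeks old. The 6 libraries formed 2 groups of 3: control scars with floxed Sox9 alleles and no Cre, and Sox9-deletion scars, in which a transgene labelled Per-Cre removed the gene from fibroblasts according to the series description. The question named in the series title is whether loss of Sox9 in fibroblasts alters the fibrotic and inflammatory state of the scar. The deposited table listed 14798 genes.

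Total counts were 18538171, 49871222 and 55523974 in control replicates 1 to 3 and 22666770, 45309194 and 48515962 in deletion replicates 1 to 3. Replicate 1 of both groups differed from the other libraries in a property of the values, and this split is called the batch here although the labels name none: every count of replicates 2 and 3 was an even number, whereas 49.9% of genes in control replicate 1 and 49.3% in deletion replicate 1 had an even count. Another way of counting mates could also give even counts, so the totals of replicates 2 and 3 may be doubled. The ribosomal precursor transcript Rn45s was at 12176 and 22484 CPM in control and deletion replicate 1, against 623 to 1004 CPM in the other 4 libraries. Xist, transcribed from the inactive X chromosome of females, was at 812 CPM in control replicate 3 and at most 7.61 CPM elsewhere, and the Y-linked helicase gene Ddx3y was at 0.596 CPM there against 122 to 146 CPM in the other 5. Control replicate 3 was therefore the 1 library with a female profile. The first principal component, with 57.2% of the variance, placed deletion replicate 1 apart from all other libraries. Rn45s, Xist and Ddx3y were named after their values were seen.

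Sox9, the transcription factor targeted in the deletion scars and best known as the regulator of cartilage matrix genes, was lower in every deletion library than in every control library. Its level was 71.1, 75.8 and 67.7 CPM in the controls and 42.1, 51.7 and 55.8 CPM in the deletion scars, a mean of 71.6 ± 4.07 against 49.9 ± 7.02 CPM (SD, n = 3 each). The log2 fold change was -0.52 ± 0.15 (SE), with an unadjusted p of 0.00985 and an edgeR adjusted p of 0.564. With the batch as a term in the model it was -0.53 (edgeR adjusted p = 0.0757), the replicate 1 pair differed by -0.76 and replicates 2 and 3 by -0.43. Over the alternatives tried, the adjusted p of Sox9 ranged from 0.00278 to 0.908 and passed 0.05 in 3 of 21. The gene lies on chromosome 11 from 112782210 to 112787757 in mm10 and shares no exonic base with another gene of the GENCODE annotation. Counts were given for the whole gene, and the deleted exons are not given in the sources used here, so transcripts of recombined alleles may still be counted. Cells of the scar without Cre activity keep their Sox9 alleles. Periostin (Postn), a matricellular protein of activated fibroblasts on chromosome 3 from 54361107 to 54391041, was at 1306 ± 398 CPM in controls and 949 ± 347 CPM in deletion scars (SD, n = 3 each), a difference of -0.46 ± 0.38 on the log2 scale (edgeR adjusted p = 0.664). Most of it came from the replicate 1 pair (-1.43), since replicates 2 and 3 gave -0.10.

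**Figure D1:**
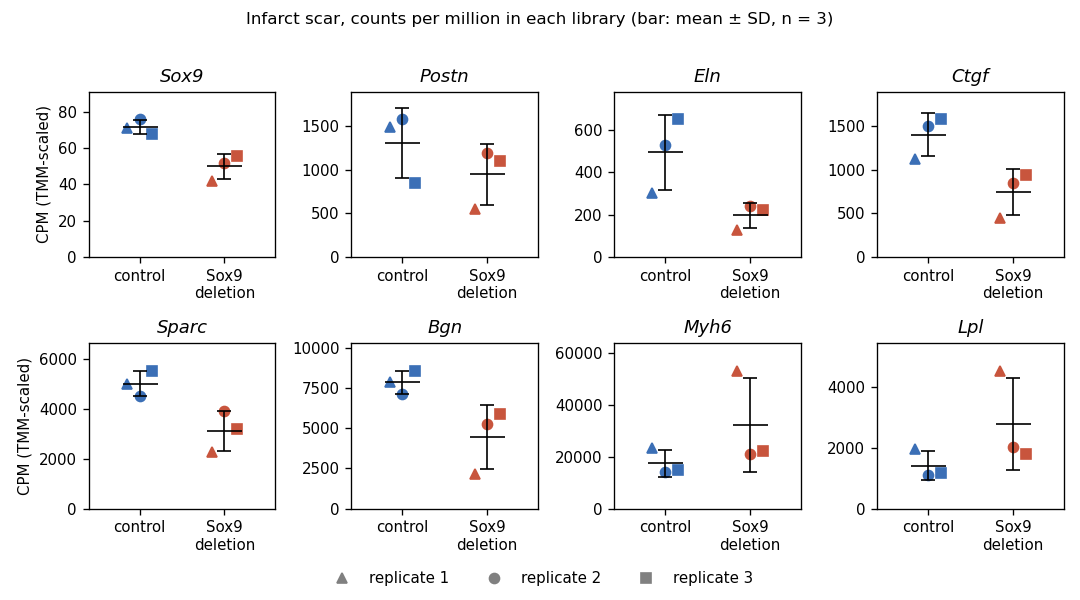
Level of 8 genes in each library, in CPM with TMM scaling on a linear axis from 0, with control libraries in blue and Sox9-deletion libraries in red. Symbols mark the replicate number and black bars the mean ± SD of 3 libraries; Sox9, Eln, Ctgf, Sparc and Bgn do not overlap between the groups, while deletion replicate 1 has the highest Myh6 and Lpl and the lowest Postn and Bgn.

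Among genes with the 100 smallest p-values, the largest differences in favour of deletion scars were in Lrtm1, Muc4, Smco1, Srrm4os and Aqp4. Lrtm1, which encodes a leucine-rich repeat membrane protein, was at 53.6 ± 50.1 CPM in controls and 647 ± 496 CPM in deletion scars. The mucin gene Muc4 was at 0.194 ± 0.0338 against 1.99 ± 1.35 CPM, Smco1 at 1.21 ± 0.261 against 11.1 ± 10.8 CPM and the water channel gene Aqp4 at 0.249 ± 0.0380 against 1.73 ± 0.882 CPM. Srrm4os, antisense to and sharing exonic bases with Srrm4, was at 0.0639 ± 0.0322 against 0.642 ± 0.495 CPM. The largest differences in favour of controls were in Lgr5, Cd209f, Myh2, Fam110c and Klk1. Lgr5, a receptor for R-spondins that potentiates Wnt signalling, was at 1.41 ± 1.16 CPM in controls and 0.137 ± 0.0194 CPM in deletion scars. The lectin gene Cd209f was at 1.77 ± 0.818 against 0.196 ± 0.133 CPM, Fam110c at 1.34 ± 0.299 against 0.246 ± 0.105 CPM and tissue kallikrein (Klk1) at 1.39 ± 0.377 against 0.255 ± 0.175 CPM. The fast skeletal myosin gene Myh2 was at 12.0 ± 7.66 against 1.83 ± 0.110 CPM. Log2 fold changes of these 10 genes were 3.60, 3.29, 3.18, 3.15 and 2.74 for the first 5 and -3.33, -3.20, -2.71, -2.36 and -2.34 for the others. The edgeR adjusted p was 0.564 for each. The groups did not overlap in any of them, which adds no support because the genes were picked by their small p-values. Some values were near the floor: Srrm4os at 0.0366 CPM in control replicate 2, Cd209f at 0.0437 CPM in deletion replicate 2 and Klk1 at 0.0528 CPM in deletion replicate 1.

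No gene passed an adjusted p of 0.05 in the edgeR quasi-likelihood test of 14771 genes, where the lowest adjusted p was 0.564. At an unadjusted p below 0.05 there were 1232 genes, 783 higher and 449 lower in deletion scars. The groups did not overlap in 17.5% of genes, 1310 higher and 1270 lower, against the 10% that chance gives on average for 3 against 3. Genes co-vary, so a single grouping can lie far from that average without an effect of genotype. The same holds for the members of a list. With a term for the batch, edgeR called 1 gene and 3348 had an unadjusted p below 0.05. That gene, named because it was the single call, was Myot, which encodes the sarcomeric Z-disc protein myotilin (log2 fold change 2.47, edgeR adjusted p = 0.0336), at 28.2, 2.56 and 3.48 CPM in the controls and 163, 15.4 and 17.4 CPM in the deletion scars. DESeq2 called 52 genes without the batch term, 33 higher and 19 lower, and 1920 with it, 1312 higher and 608 lower. Replicates 2 and 3 alone gave 0 calls with edgeR and 2342 genes at an unadjusted p below 0.05.

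Genes of the contractile apparatus and of mitochondrial energy metabolism were higher on average in deletion scars. All 33 measured genes of oxidative phosphorylation and the citrate cycle, all 33 cardiomyocyte contractile and calcium-handling genes and 27 of 28 fatty acid oxidation genes had positive log2 fold changes. As lists, all 3 rose with a preset correlation in camera, with median log2 fold changes of 0.85 (adjusted p = 1.12e-14), 0.77 (adjusted p = 2.33e-11) and 1.03 (adjusted p = 1.36e-10). Each of the 3 calls was lost when the correlation was estimated (adjusted p = 0.603 with an estimated correlation). The heavy chain gene Myh6, the adult alpha myosin of mouse ventricle, was at 17430.1 ± 5126 CPM in controls and 32142 ± 18166 CPM in deletion scars, and Myh7, the beta heavy chain, at 12792 ± 1458 against 15828 ± 3311 CPM. The ATP synthase subunit genes Atp5b and Atp5a1 were at 1535 ± 432 against 2482 ± 935 CPM and 1410.4 ± 347 against 2351 ± 847 CPM. Lipoprotein lipase (Lpl) was at 1405 ± 477 against 2772 ± 1524 CPM and the fatty acid translocase gene Cd36 at 869 ± 477 against 1529.9 ± 799.9 CPM. No member passed over all genes tested; adjusted over the list alone, 2 fatty acid oxidation genes passed, the nuclear receptor Ppara and its coactivator Ppargc1a, and no member of the other 2 lists did. With the batch term, 33 oxidative phosphorylation, 27 cardiomyocyte and 26 fatty acid oxidation genes passed over the list alone. The groups did not overlap in 16, 10 and 6 members of the 3 lists, higher in deletion scars, against 17.5% of all genes and 10% by chance in both directions together. The replicate 1 pair had list medians of 1.10, 0.75 and 1.25, and replicates 2 and 3 had 0.63, 0.69 and 0.79. Without deletion replicate 1, whose Myh6 level was 53109.8 CPM against 14019.7 to 23326 CPM in the other libraries, the medians were 0.44, 0.31 and 0.45. The top of that range was control replicate 1, above deletion replicates 2 (21118 CPM) and 3 (22199 CPM). Its cardiomyocyte and fatty acid oxidation scores, 0.122 and 0.142, also exceeded those of deletion replicates 2 (0.117 and 0.125) and 3 (-0.005 and -0.047). Its oxidative phosphorylation score, -0.026, lay between theirs (0.171 and -0.038). With the cardiomyocyte score as a covariate, oxidative phosphorylation was at 0.0791 (camera adjusted p = 0.258) and fatty acid oxidation at -0.0303 (camera adjusted p = 0.713). Scores of these 2 lists followed the cardiomyocyte score. They were -0.76 and -0.93 against -0.69 in control replicate 2, and 1.13 and 1.34 against 1.01 in deletion replicate 1. Their loss under the covariate therefore cannot separate them from the cardiomyocyte list. Without the covariate, the collagen and fibroblast lists moved the other way in the same libraries (medians -0.54 and -0.41). The cardiac stress list, which holds natriuretic peptide genes and the ankyrin repeat gene Ankrd1, did not pass, with a median of -0.02 over 10 genes (adjusted p = 0.681), and Ankrd1 was at 8251 ± 2493 against 9232 ± 2028 CPM.

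Structural matrix genes were lower on average in deletion scars. All 18 non-cartilage collagen genes, 30 of 34 matricellular and glycoprotein genes, 22 of 24 genes of collagen processing and cross-linking, 20 of 23 proteoglycan genes and 30 of 37 genes of matrix proteases and their inhibitors had negative log2 fold changes. As lists, all 5 fell with a preset correlation, with medians of -0.54 (adjusted p = 7.08e-07), -0.66 (adjusted p = 2.16e-07), -0.50 (adjusted p = 5.82e-06), -0.52 (adjusted p = 0.00331) and -0.43 (adjusted p = 3.20e-05). None of the 5 held with an estimated correlation (adjusted p = 0.603 with an estimated correlation for each). Proteoglycan scores overlapped between the groups, at -0.099 in control replicate 1 against 0.201 in deletion replicate 3. The fibrillar collagen genes Col3a1 and Col1a2 were at 4183 ± 638 against 2944 ± 1394 CPM and 2506 ± 302 against 1665 ± 810.5 CPM. Sparc, a collagen-binding matricellular protein, was at 5006 ± 503 CPM in controls and 3114 ± 807 CPM in deletion scars, with a log2 fold change of -0.68 ± 0.28 (SE), and the groups did not overlap. The same held for biglycan (Bgn), a small leucine-rich proteoglycan, at 7846 ± 728 against 4426 ± 1996 CPM, and for the metalloproteinase inhibitor Timp3, at 1348 ± 107 against 813 ± 317 CPM. Decorin (Dcn) was at 3167 ± 433 against 2562 ± 738 CPM, the lysosomal protease gene Ctsd at 767 ± 57.7 against 820.1 ± 95.8 CPM, the prolyl hydroxylase subunit gene P4hb at 749 ± 58.4 against 574 ± 141 CPM and the collagen chaperone gene Serpinh1 at 689 ± 126 against 548 ± 147 CPM. Elastin (Eln), chosen after its values were seen, was at 493 ± 178 against 197 ± 59.8 CPM, with a log2 fold change of -1.32 ± 0.36 (SE) that was -1.22 in the replicate 1 pair and -1.36 in replicates 2 and 3. No member of the 5 lists passed over all genes tested, and 0 passed when adjusted over the list alone. With the batch term, 1 collagen, 8 matricellular, 3 collagen processing, 6 proteoglycan and 0 protease genes passed over the list alone, counted in either direction. The groups did not overlap, with controls higher, in 6, 13, 10, 4 and 11 members in the same order of lists, against 17.5% of all genes and 10% by chance in both directions together. With the cardiomyocyte score as a covariate the medians were -0.37, -0.27, -0.15, 0.0423 and -0.15 in the same order, with none called. The cardiomyocyte list had the opposite direction in the same libraries, and its mean level above the average of the 6 libraries was 1.01 in deletion replicate 1, the library with the lowest collagen level (-1.08). The replicate 1 pair had medians of -1.37, -1.40, -1.03, -0.82 and -0.89, and replicates 2 and 3 had -0.28, -0.44, -0.21, -0.39 and -0.26. Without deletion replicate 1 the medians were -0.39 for the collagens, -0.35 for the matricellular genes, -0.24 for collagen processing and -0.31 for the proteases. The proteoglycans were at -0.21 there and no longer passed (camera adjusted p = 0.0518). The collagens moved to -0.85 without deletion replicate 2. Without deletion replicate 1 the log2 fold changes of Col3a1 and Dcn went from -0.51 and -0.31 to -0.20 and -0.0940.

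**Figure D2:**
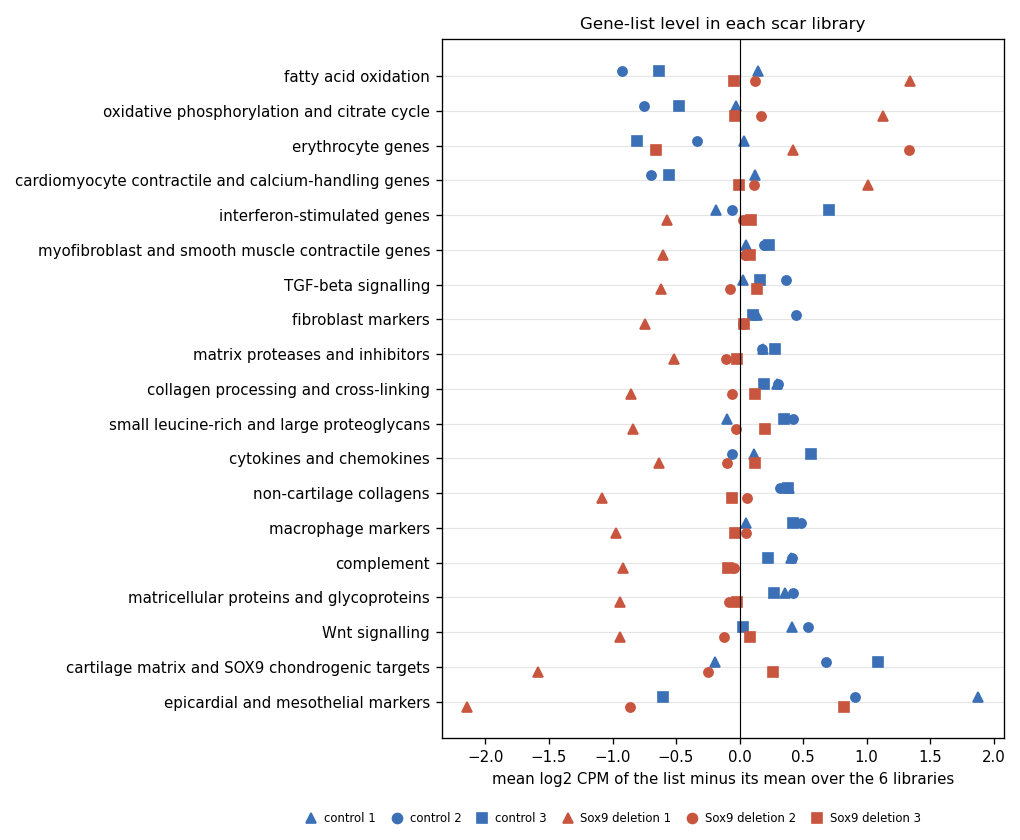
Level of the 19 lists that passed camera with a preset correlation, as the mean log2 CPM of the list's genes in each library minus its mean over the 6 libraries, for control (blue) and Sox9-deletion (red) libraries with symbols for the replicate number. Deletion replicate 1 has the lowest level of the collagen list, at -1.08, and the highest of the cardiomyocyte list, at 1.01, while deletion replicates 2 and 3 lie between it and the controls for the collagens.

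Fibroblast, transforming growth factor beta, Wnt and cartilage genes were also lower on average in deletion scars. Of the measured members, 24 of 26 fibroblast markers, 15 of 20 myofibroblast and smooth muscle contractile genes, 25 of 29 TGF-beta signalling genes, 20 of 24 Wnt signalling genes and 21 of 23 cartilage matrix genes and SOX9 chondrogenic targets had negative log2 fold changes. These 5 lists fell with a preset correlation, with medians of -0.41 (adjusted p = 0.000161), -0.35 (adjusted p = 0.0141), -0.40 (adjusted p = 6.60e-05), -0.70 (adjusted p = 0.000684) and -0.83 (adjusted p = 0.000106). Each call was lost when the correlation was estimated (adjusted p = 0.603 with an estimated correlation). Fibroblast scores did not overlap between the groups, whereas those of the other lists did. The myofibroblast, TGF-beta and cartilage scores were 0.054, 0.030 and -0.193 in control replicate 1 against 0.079, 0.134 and 0.261 in deletion replicate 3. The Wnt score was 0.030 in control replicate 3 against 0.082 in deletion replicate 3. Connective tissue growth factor (Ctgf), a direct TGF-beta target, was at 1398 ± 242 CPM in controls and 744 ± 263 CPM in deletion scars, with a log2 fold change of -0.91 ± 0.33 (SE) and no overlap between groups. The integrin subunit gene Itgb5 was at 537 ± 108 against 346 ± 147 CPM. Sfrp2, a secreted Frizzled-related protein, was at 639 ± 356 against 294 ± 196 CPM, and beta-catenin (Ctnnb1) at 627 ± 55.1 against 578 ± 35.4 CPM. Among fibroblast markers the actin-severing protein gene Gsn was at 3030.2 ± 521 against 2293 ± 557 CPM. The 2 most abundant members of the myofibroblast list, Tpm1 and Des, are also expressed by cardiomyocytes and had positive log2 fold changes of 0.51 ± 0.37 and 0.25 ± 0.34 (SE). Tpm1 was at 0.25 without deletion replicate 1 and Des at 0.00830 without control replicate 3. Cartilage oligomeric matrix protein (Comp) was at 905 ± 388 against 449 ± 362 CPM and Cilp at 656 ± 119.8 against 492 ± 191 CPM. The type II collagen gene Col2a1, a direct SOX9 target in cartilage that was named after its values were seen, was at 1.39, 5.74 and 29.3 CPM in controls and 0, 0.699 and 0.845 CPM in deletion scars, with the highest value in control replicate 3. Aggrecan (Acan) and Col9a2, also named after their values were seen, were at 13.1 ± 6.54 against 6.06 ± 4.21 CPM and 4.06 ± 1.02 against 0.941 ± 0.476 CPM. No member of these 5 lists passed over all genes or when adjusted over the list alone. In the same order, the groups did not overlap in 3, 6, 6, 5 and 4 members with controls higher. With deletion scars higher they did not overlap in 0, 2, 2, 0 and 1, against 17.5% of all genes in both directions together. With the batch term, 4 fibroblast, 10 myofibroblast, 1 TGF-beta, 3 Wnt and 7 cartilage genes passed over the list alone. These counts take both directions together and include Tpm1, which was higher in deletion scars (log2 fold change 0.54 with the batch term). Of all 14771 genes in that edgeR fit, 3348 had an unadjusted p below 0.05. The cardiomyocyte list moved the other way in the same libraries (median 0.77), and with its score as a covariate the medians were 0.0196 for fibroblast, -0.0466 for myofibroblast, 0.0339 for TGF-beta, -0.0205 for Wnt and 0.21 for cartilage genes, with none called. The SOX family list, which includes Sox9 itself, did not pass, with a median of 0.29 over 11 members (adjusted p = 0.481), and Sox4 was at 21.3 ± 1.25 against 20.3 ± 1.40 CPM. In the order given, the replicate 1 pair had medians of -0.65, -0.80, -0.80, -1.56 and -1.22 and replicates 2 and 3 had -0.24, -0.21, -0.27, -0.42 and -0.58. Without deletion replicate 1 they were -0.20, -0.14, -0.19, -0.43 and -0.45, and the cartilage list was at -0.46 without control replicate 3.

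Macrophage, complement, cytokine and interferon-stimulated genes were lower on average in deletion scars, and monocyte, neutrophil and mast cell markers did not pass. All 30 macrophage markers, 20 of 22 complement genes, 30 of 37 cytokine and chemokine genes and 27 of 29 interferon-stimulated genes had negative log2 fold changes. The 4 lists fell with a preset correlation, with medians of -0.55 (adjusted p = 5.82e-06), -0.58 (adjusted p = 2.46e-05), -0.54 (adjusted p = 0.00526) and -0.34 (adjusted p = 0.00184). The first 3 were lost when the correlation was estimated (adjusted p = 0.603 with an estimated correlation), as was the interferon list (adjusted p = 0.662 with an estimated correlation). Interferon scores were -0.184, -0.062 and 0.705 in control replicates 1 to 3 and -0.574, 0.027 and 0.089 in deletion replicates 1 to 3. Cytokine scores overlapped as well, with -0.058 in control replicate 2 against 0.118 in deletion replicate 3. Macrophage and complement scores did not overlap between the groups. The macrophage scores nearly met, at 0.055 in control replicate 1 and 0.047 in deletion replicate 2. With controls higher, the groups did not overlap in 4 macrophage, 5 complement, 6 cytokine and 3 interferon-stimulated genes. With deletion scars higher they did not overlap in 1 complement gene, against 17.5% of all genes in both directions together. Lysozyme 2 (Lyz2) was at 877 ± 435 CPM in controls and 614 ± 248 CPM in deletion scars and the leukocyte membrane protein gene Laptm5 at 215 ± 117 against 130.2 ± 54.2 CPM. Their log2 fold changes of -0.51 and -0.72 were -0.0598 and -0.19 without control replicate 3. Complement C3 did not overlap between the groups, at 2724 ± 323 against 1600.0 ± 679.7 CPM. The chemokine genes Cxcl14 and Ccl21a were at 178 ± 158 against 187 ± 66.0 CPM and 134 ± 22.9 against 153 ± 46.0 CPM, the latter with near-identical copies in the genome. The interferon-induced GTPase gene Gbp2 was at 132 ± 79.1 against 93.4 ± 38.6 CPM. No member of these lists passed over all genes or when adjusted over the list alone. With the batch term, 10 complement, 2 interferon-stimulated, 0 macrophage and 0 cytokine genes passed over the list alone, counted in either direction. The cardiomyocyte list moved the other way (median 0.77), and with its score as a covariate macrophage genes were at 0.0582, complement at -0.0142, cytokines at -0.15 and interferon-stimulated genes at 0.19, with none called. The lists of T and natural killer cells (median -0.80, adjusted p = 0.115), antigen presentation (-0.60, adjusted p = 0.120), monocytes and neutrophils (-0.20, adjusted p = 0.732), B and plasma cells (0.41, adjusted p = 0.891) and mast cells (-0.77, adjusted p = 0.210) did not pass, and the B cell median had the opposite sign to the camera direction. Leaving out 1 library turned each of these lists but that of monocytes and neutrophils into a call. The direction of the call depended on the library for T and natural killer cells, antigen presentation and B cells. The mast cell list passed without control replicate 3 (-1.31, adjusted p = 0.00460) or deletion replicate 3 (-1.72, adjusted p = 0.0438). Cd4 and the regulatory T cell factor Foxp3 had log2 fold changes of -0.95 ± 1.02 and -0.50 ± 0.46 (SE), and the class I genes B2m and H2-D1 at 1253 ± 826 against 1007 ± 339 CPM and 900.4 ± 696 against 739.8 ± 381 CPM, with the highest level of all 4 genes in control replicate 3. Itgam and Ccr2, of myeloid cells, had log2 fold changes of -0.87 ± 0.39 and -0.76 ± 0.67 (SE). Xbp1 and Ebf1, from the B and plasma cell list, were at -0.44 ± 0.19 and -0.02 ± 0.21. Kit and Gata2, from the mast cell list, were at -0.54 ± 0.41 and 0.61 ± 0.37. Counts of whole scar tissue do not show which cells these transcripts came from. Without control replicate 3, Ccr2 was at -0.0204 and Kit at -0.12. The replicate 1 pair had medians of -0.78, -1.001, -0.50 and -0.28 for macrophage, complement, cytokine and interferon genes, and replicates 2 and 3 had -0.52, -0.41, -0.36 (adjusted p = 0.0539) and -0.28. Without deletion replicate 1 the first 3 were -0.34, -0.29 and -0.36 and the interferon list no longer passed (adjusted p = 0.0735), and without control replicate 3 the macrophage list was at -0.28, while the cytokine list at -0.24 (adjusted p = 0.105) and the interferon list at -0.07 (adjusted p = 0.726) no longer passed. The cytokine call was also lost with members at or above the median expression (adjusted p = 0.0878).

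Of the remaining cell types, epicardial and mesothelial markers fell and erythrocyte genes rose with a preset correlation, and the others did not pass. All 15 epicardial genes had negative log2 fold changes, with a median of -1.16 (adjusted p = 0.000168, and adjusted p = 0.603 with an estimated correlation). Tbx18 and the retinoic acid synthesis gene Aldh1a2 were at 25.3 ± 6.22 against 17.5 ± 5.61 CPM and 29.3 ± 22.0 against 12.5 ± 1.84 CPM. All 10 erythrocyte genes had positive log2 fold changes, with a median of 0.81 (adjusted p = 0.0247, and adjusted p = 0.619 with an estimated correlation). The alpha-globin genes Hba-a1 and Hba-a2, near-identical copies that the table places at nearly the same coordinates, were at 1134 ± 477 against 2307 ± 1635 CPM and 1128 ± 474 against 2293 ± 1625 CPM. No member of either list passed over all genes or when adjusted over the list alone. The epicardial median was -4.07 in the replicate 1 pair and -0.37 in replicates 2 and 3 (adjusted p = 0.572), and it was -0.49 without control replicate 1 and -1.99 without deletion replicate 3. The erythrocyte median was 0.41 in the replicate 1 pair and 0.89 in replicates 2 and 3 (adjusted p = 0.0539), and the call was lost without deletion replicate 1 (median 0.57), deletion replicate 2 (median 0.34) or control replicate 3 (median 0.48). With the cardiomyocyte score as a covariate neither list passed (erythrocyte median 0.17, adjusted p = 0.854; epicardial median -0.86, adjusted p = 0.158). The erythrocyte call was also lost with the batch term (adjusted p = 0.0728), and the epicardial call was lost with members at or above the median expression (adjusted p = 0.0878).

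Endothelial markers had a median log2 fold change of 0.30 (adjusted p = 0.141), lymphatic endothelial markers -0.47 (adjusted p = 0.143), pericyte markers 0.06 (adjusted p = 0.732), Schwann cell markers 0.13 (adjusted p = 0.891) and adipocyte markers 0.33 (adjusted p = 0.732, with a negative camera direction and a mean of -1.49). The endothelial list passed without deletion replicate 2 (0.43, adjusted p = 0.0306) or 3 (0.42, adjusted p = 0.0255) and was at -0.06 without deletion replicate 1. The lymphatic list passed without control replicate 1 (-0.65, adjusted p = 0.0226) and in replicates 2 and 3 (-0.59, adjusted p = 0.0119). Among their most abundant genes, Fabp4, of capillary endothelium and fat, was at 366 ± 206 against 547 ± 314 CPM. Its log2 fold change of 0.58 was 0.0182 without deletion replicate 1 and 1.15 without control replicate 1. The lymphatic receptor gene Lyve1 was at 100.2 ± 33.0 against 59.7 ± 26.6 CPM, the pericyte gene Rgs5 at 584 ± 141 against 749 ± 296 CPM, and Pdgfrb, shared by pericytes and fibroblasts, at 271 ± 44.3 against 199 ± 39.9 CPM without overlap. The lipase gene Pnpla2 had a log2 fold change of 0.45 ± 0.33 and the myelin genes Pmp22 and Cnp -0.24 ± 0.29 and -0.28 ± 0.26 (SE). Adjusted over the list alone, 1 Schwann cell gene passed, S100b with a log2 fold change of -1.16, and no member of these lists passed over all genes tested. With the batch term, 4 endothelial, 2 pericyte, 5 adipocyte and 1 Schwann cell genes passed over the list alone, as did 9 skeletal muscle, 2 bone and 2 cardiac stress genes. Skeletal muscle genes split, with the fast myosin Myh2 lower and the muscle enzymes Pygm (0.86 ± 0.37) and Eno3 (1.46 ± 0.51) higher on the log2 scale, and the list did not pass (median -0.75, adjusted p = 0.421). It passed without control replicate 3 (-0.96, adjusted p = 0.0323) or deletion replicate 1 (-1.04, adjusted p = 0.0476) and was at 0.14 without control replicate 1. Bone and calcification genes had a median of -0.41 (adjusted p = 0.115) and passed without control replicate 2 (-0.54, adjusted p = 0.0300) or deletion replicate 1 (-0.19, adjusted p = 0.0476). Matrix Gla protein (Mgp), an inhibitor of calcification, was at 2580.4 ± 622 against 1326 ± 580.1 CPM without overlap. The pyrophosphate transporter gene Ank was at 113 ± 11.1 against 147 ± 48.1 CPM. Only 4 of 16 epithelial, thyroid or lung genes were measured (median -0.46, adjusted p = 0.348), with Krt14 at 1.56 ± 1.71 against 1.33 ± 1.57 CPM and Cdh1 at 1.57 ± 1.59 against 0.670 ± 0.555 CPM. Proliferation genes had a median of -0.19 (adjusted p = 0.421), with Pcna at 53.0 ± 4.98 against 48.5 ± 1.51 CPM and Mki67 at 39.2 ± 20.6 against 38.0 ± 9.53 CPM. Cytosolic ribosomal protein genes had a median of -0.09 (adjusted p = 0.103), with Rpl4 and Rpl5 at -0.10 ± 0.17 and -0.14 ± 0.17 on the log2 scale. Immediate early and stress genes had a median of 0.51 (adjusted p = 0.0592), -0.07 without deletion replicate 1 and -0.18 in replicates 2 and 3 (adjusted p = 0.0110, in the lower direction). Egr1 was at 949.7 CPM in deletion replicate 1 and 71.0 to 96.2 CPM in the other 5 libraries. Hspa8 was at 3738 ± 678 against 4014 ± 368 CPM. None of the 13 mitochondrially encoded genes was in the table, so that list was not analysed here.

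The authors' deposited table gives its own log2 fold changes, which equal the ratio of its group means of TMM values, and a NOISeqBIO probability for each gene. In the authors' deposited table Sox9 had a log2 fold change of -0.55, Postn -0.55, Col3a1 -0.63, Sparc -0.73, Ctgf -0.99, C3 -0.86, Myh6 0.76 and Lpl 0.88. In the table deposited by the authors, 11697 genes, 79.0% of those listed, had a probability of at least 0.95, 5183 higher and 6514 lower in deletion scars, and 861 of them had an absolute log2 fold change of at least 1. The sign of the fold change was the same in the authors' deposited table and in the edgeR fit for 96.6% of genes tested. On the counts of the same libraries edgeR called 0 genes (1232 at an unadjusted p below 0.05), DESeq2 52, and with the batch term edgeR 1 and DESeq2 1920. The TMM values of the authors were not the counts times a factor per library. Over the 9182 genes with a mean count above 500, 99.98% of the gene-wise variance of the ratio between TMM value and count lay in a single pattern that set replicate 1 of both groups against replicates 2 and 3. Across genes, the correlation of these values with TMM-scaled log2 CPM was at least 0.999 in each library once the batch difference had been subtracted, and as low as 0.557 before, where genes are not independent replicates. After the adjustment the replicate 1 libraries of the 2 groups deviated from their group means in opposite directions, with a correlation across genes of -0.994 against 0.482 in the counts. Subtracting a batch that holds 1 library of each group forces such opposite deviations, so this correlation is no separate evidence.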

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

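Tests chosen after the data were seen are the batch term, replicates 2 and 3 alone, halved counts, DESeq2 and limma with a batch term, limma on the values of the authors, on log2 CPM and on log2 CPM after subtraction of the batch, the adjusted p below 0.10 with the batch term, and the cardiomyocyte score as a covariate; fry was fixed beforehand beside camera and listed as an alternative later. Sox9 stayed lower in all 21 alternatives run. Library size factors of DESeq2, no low-count filter, coding transcripts only, a median log2 fold change of 0 and halved counts kept all 19 list calls. Each left-out library leaves 2 against 3, and replicates 2 and 3 alone 2 against 2, so a lost call there comes with fewer samples. For the other moves below, the cause was not tested. Alternatives prepared for a table of normalized values or of group means only (pseudocounts of 0.1 and 1, filters on means, fold scales, probability thresholds and random lists) were not run, since counts were given.

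Calls of genes, 0 with edgeR and genotype alone, were 52 with DESeq2, 1920 with DESeq2 and a batch term, 1 with the edgeR batch term, 1 with halved counts and a batch term, 1086 with the batch term at an adjusted p below 0.10, 1576 with limma on the values of the authors, 1 with limma on log2 CPM with a batch term and 1700 after subtraction of the batch. Genes at an unadjusted p below 0.05, 1232 in the edgeR fit, were 3760 with DESeq2 and a batch term, 3348 with the edgeR batch term, 3356 with halved counts and a batch term, 2342 in replicates 2 and 3, 4638 with limma on the values of the authors, 3464 with limma and a batch term, 4626 after subtraction of the batch and 452 to 1726 in leave-one-out fits. Sox9 passed an adjusted p of 0.05 with DESeq2 and a batch term (log2 fold change -0.52), limma on the values of the authors (-0.55) and limma after subtraction of the batch (-0.53).

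With the replicate number as a block, 0 genes were called by edgeR and 2560 had an unadjusted p below 0.05, and Mki67 turned to 0.0672. The block kept all 19 list calls and added T and natural killer cells (adjusted p = 0.0484) and antigen presentation (adjusted p = 0.0108). Same-numbered libraries of the 2 groups deviated together with correlations of 0.482, 0.0131 and 0.180 for numbers 1 to 3. The number 1 pair is also the batch, and controls 2 and 3 correlated best with another number (0.308 and 0.393). Deviations of 3 libraries from their group mean sum to 0, so these correlations cannot settle whether the numbers pair the libraries.

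Log2 fold changes that turned sign were Krt14 at 0.12 with DESeq2 and a batch term, 0.23 with the edgeR batch term, 0.11 with halved counts and a batch term and 1.69 in replicates 2 and 3, and Mki67 at 0.0456 with DESeq2 and a batch term, 0.0399 with the edgeR batch term, 0.0428 with halved counts and a batch term, 0.0521 with limma on the values of the authors and 0.0734 with limma on log2 CPM, with a batch term and after its subtraction. In replicates 2 and 3, Ccl21a was at -0.23, Ebf1 at 0.19, Hspa8 at -0.0315, Egr1 at -0.23 and the immediate early list at -0.18, where it passed in the lower direction; it passed in the higher direction without control replicate 2 or 3 or deletion replicate 2 or 3. Leave-one-out fits spanned -0.27 to 1.11 for Cxcl14, -0.00980 to 0.16 for Ctsd, -0.83 to 0.10 for Gbp2, -0.0171 to 0.55 for Rgs5, -1.58 to 1.16 for Krt14, -1.74 to 0.0961 for Cdh1, -0.0921 to 0.34 for Ccl21a, -0.18 to 0.0996 for Ebf1, -0.12 to 2.63 for Egr1, -2.28 to 3.32 for Rn45s, -1.45 to 1.08 for Cd4, -0.77 to 0.23 for Foxp3, -0.59 to 0.38 for B2m, -0.65 to 0.55 for H2-D1, -0.37 to 0.40 for Mki67, -0.0327 to 0.22 for Hspa8 and -7.50 to 1.15 for Xist.

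Lists called, 19 at the preset correlation, were 0 with an estimated correlation, 0 with fry, 18 with the batch term (0 with the batch term and an estimated correlation), 20 in replicates 2 and 3 (16 shared) and 4 with the cardiomyocyte score as a covariate. None of those 4 (B cells, antigen presentation, adipocytes and skeletal muscle) is among the 19, so 0 of the 19 calls were kept under the covariate, which the cardiomyocyte list loses by construction. The score also differs between the groups, so a call lost under it does not show that genotype made no difference. The call lost with the batch term was that of erythrocyte genes (adjusted p = 0.0728, and 0.0996 with halved counts and a batch term). With the cardiomyocyte covariate the medians were 0.21 for cartilage, 0.0423 for proteoglycans, 0.0196 for fibroblast, 0.0339 for TGF-beta, 0.0582 for macrophage, 1.80 for B cell, 0.63 for antigen presentation, 0.19 for interferon, -0.0303 for fatty acid oxidation and -0.0466 for myofibroblast genes, the last with a positive camera direction. With members at or above the median expression, the skeletal muscle list was at 1.29 and passed, and the epicardial and cytokine lists no longer passed (adjusted p = 0.0878 for both). Leave-one-out medians spanned -1.30 to 0.76 for T and natural killer cells, -1.02 to 0.50 for antigen presentation, -0.43 to 0.17 for proliferation and -0.48 to 1.11 for B cells. Antigen presentation passed in the lower direction without control replicate 1 (-1.02, 0.00225), control replicate 2 (-0.89, 0.00772) or deletion replicate 3 (-0.82, 0.0299) and in the higher without control replicate 3 (0.50, 0.0297), as median and camera adjusted p. Proliferation passed lower without control replicate 1 (-0.43, 0.00162) and in replicates 2 and 3 (-0.29, 0.00762) and higher without control replicate 3 (0.17, 0.0198). B cells passed higher without deletion replicate 1 (0.75, 0.00838) and lower without deletion replicate 2 (-0.48, 0.0328), and ribosomal proteins lower without control replicate 1 (-0.14, 0.0128) and in replicates 2 and 3 (-0.15, 0.00317).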

Other observations

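The test of the subtracted batch was chosen after its result was seen, as were the libraries singled out in this paragraph. Lymphocyte and antigen presentation genes stood apart in 1 control scar. The T and natural killer cell score was 1.91 in control replicate 3, the library with the female profile, and -1.04 to 0.21 in the others, and the antigen presentation score was 1.71 against -1.24 to 0.40. Without that library the T and natural killer cell median was 0.76 (camera adjusted p = 0.0110), opposite in sign to the -0.80 of all 6 libraries (camera adjusted p = 0.115, and 0.864 with an estimated correlation). The list passed in the lower direction without control replicate 1 (-1.30, camera adjusted p = 0.0133), control replicate 2 (-1.26, 0.000347) or deletion replicate 2 (-0.97, 0.0387). The B and plasma cell score was highest in deletion replicate 2 (1.54) and lowest in deletion replicate 1 (-1.67). Adipocyte and epicardial scores were highest in control replicate 1 (2.01 and 1.88), and the epicardial score was lowest in deletion replicate 1 (-2.14). Deletion replicate 1 also had the highest immediate early score (1.15), and the erythrocyte score was highest in deletion replicate 2 (1.34).

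The 5 matrix lists together, with 135 measured genes, had a median log2 fold change of -0.533 (95% interval over genes -0.574 to -0.488). It was -0.293 (-0.373 to -0.233) without deletion replicate 1 and -0.490 (-0.542 to -0.414) without control replicate 3, so its sign held without either library. These intervals hold no spread between libraries, so they cannot exclude that deletion replicate 1 carried much of the difference. With the cardiomyocyte score as a covariate the median was -0.147 (-0.229 to -0.028), an interval that meets neither bound set for a larger share of myocardium in the deletion samples. That explanation cannot be told apart from lower matrix expression per cell, because the score differs between the groups. A biological effect of Sox9 loss on matrix genes was not tested apart from it.

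The cardiomyocyte, oxidative phosphorylation and fatty acid oxidation lists together, with 94 measured genes, had a median of 0.882. It was 0.427 (0.387 to 0.459) without deletion replicate 1 and 0.820 (0.773 to 0.875) without control replicate 3, so its sign held without either library. Here too the intervals hold no spread between libraries and cannot exclude that deletion replicate 1 carried much of the difference. Whether the scars of the 2 groups were dissected with different amounts of surviving myocardium was not tested, since no measure of it other than these genes is in the table. Sox9 loss as a biological explanation was not tested apart from it.

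The values of the authors gave 1576 calls with limma where the counts gave 0 (1154 at an unadjusted p below 0.05; edgeR 0 and 1232, DESeq2 52). Subtraction of the batch from log2 CPM before the test gave 1700 calls, against 1 with the same batch as a term in the model; at an adjusted p below 0.10 these were 3259 and 1189, a smaller gap. This is consistent with a batch subtracted before the test, which leaves the degree of freedom it used uncounted. The submitters' steps for these values are not given in the sources used here.

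A design of 3 libraries against 3 makes 10 splits, too few for a share under 0.05. For genes past an adjusted p of 0.05 the real split gave 0 and the highest other 0, so that 10 of 10 gave as many. For genes at an unadjusted p below 0.05 the real split gave 1232 and the highest other 2240, with 2 of 10 as large. That other split puts both replicate 1 libraries with deletion replicate 2, and with the batch term in the model the real split gave 3348. The other splits were not run with the batch term, so 3348 cannot be set against their counts. For lists the real split gave 19 and the highest other 25, with 7 of 10 as large.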
